A study of Mus musculus with 2 samples.

How the data were processed

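Mammary glands of Nfatc1-CreERT2; R26-tdTomato mice were digested to single cells, and cells carrying the red reporter were sorted and profiled with 10x Chromium Single Cell 3′ v2 chemistry, per the labels' protocols. In such mice an inducible Cre recombinase made under the Nfatc1 gene switches on the tdTomato reporter, which descendants of the marked cells keep. The sort excluded cells positive for CD45 (leukocytes), CD31 (endothelium) and Ter119 (red cells) and kept cells positive for CD29, CD24 and the red reporter. There were 2 libraries, 1 per group: marked cells at 8 weeks of age and marked-cell descendants at pregnancy day 14.5. The labels call the first group untreated. They give no age for the pregnant mice, so age cannot be told apart from pregnancy in any difference between the libraries.

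The deposited values were UMI counts (unique molecular identifiers, each 1 captured transcript) per gene and barcode, with no normalization. The submitters' processing notes name Cell Ranger 2.0.1 and mm10 for both libraries, whereas per the file headers the pregnant library was written by software version 3.1.0. Genes listed were 27998 at 8 weeks and 31053 in pregnancy; comparisons used the 27514 IDs present in both, which held 99.6% and 99.8% of the UMIs of called barcodes. For each library both the authors' called barcodes and the counts of all barcodes were used. The raw barcode list held 737280 barcodes, and 0 called barcodes had a total that differed between the called and raw tables.

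Called barcodes with at least 500 genes and under 10% mitochondrial UMIs were kept, and Scrublet (in scanpy 1.11.5) removed doublets per library: 9 barcodes, 0.348%, in the 8-week library and 66, 0.976%, in the pregnant library. Each library was clustered alone from counts scaled to 10000 per cell and logged, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0 (igraph 0.11.9, python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). Clusters were named from 15 marker lists written before the data were examined. The scoring was set after a first look: a marker counted when its cluster level was at least 4-fold above the 20th percentile of clusters, a name needed 3 such markers and a mean log2 of at least 1, and a cluster whose 10 leading genes held more markers of another class stayed unnamed. This left 12.9% of 8-week cells and 0 pregnant cells unnamed. Red-cell markers were left out of that last check, also after a first look, because 1 barcode with 5247 haemoglobin UMIs out of 5250 in its cluster of 218 cells put haemoglobin genes among the leading genes of a pregnant cluster; without barcodes of 50 or more haemoglobin UMIs its leading genes were Top2a and Cdk1.

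Counts were summed per library and class and given as CPM, the count scaled to a fixed class total, with exact Poisson intervals. Ratios are pregnant over 8-week with exact conditional binomial intervals, and shares have exact Clopper-Pearson intervals. All intervals are at 95% and cover counting error alone. With 1 library per group there is no test between groups: each difference is between 2 libraries, and no p-value, standard error or number of changed genes was derived from cells. Log2 ratios used a pseudocount of 10 CPM. A gene at 0 counts was set to 3 counts of its class total to give a lower bound of the fold. The exact interval of such a fold starts lower. Genes were named by a fixed rule: at least 50 CPM and 30 counts in the higher library, a class level of at least 0.5 of the CPM of that library's empty droplets, and the 12 highest and 12 lowest log2 ratios, leaving out ribosomal, mitochondrial, haemoglobin and predicted genes and pseudogenes. Nfatc1 and 2 to 4 members of each list with the largest ratios were added.

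The 24 gene lists were also written before the data were examined. For each, the median log2 ratio over members with at least 10 CPM in either library was placed among 10000 random lists of the same size drawn from the same 20 bins of expression, and a list is called apart when it lies outside the central 95%. These percentiles describe these libraries. A list needed 5 measured members. A member counted as higher or lower when its ratio was at least 2 either way and its interval excluded 1. Medians have intervals from 200 Poisson redraws.

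Cycling was scored as the share of cells with 3 or more UMIs over the G2/M list after every cell was thinned to 3300 UMIs, leaving out shallower cells. Empty droplets were barcodes outside the called list with 1 to 50 UMIs: 270952 barcodes with 1921501 UMIs in the 8-week library and 408026 with 1050701 in the pregnant library. The background share of a class was the CPM of markers it should lack over their CPM in the empty droplets: 14 fibroblast and endothelial genes for epithelial classes, and 11 keratin, Epcam and claudin genes for the others. Subtraction of this background was chosen after seeing the data. The list minimum of 10 CPM was applied again to subtracted levels, so the measured members of a list could differ from those as counted. Positions are from the GENCODE vM21 annotation of GRCm38 (mm10), in which all 55 genes named by the size rule were found by ID.

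The steps were tested on simulated data drawn from these libraries, pooling 20 draws of 200 changed genes each; a first single draw had given lower interval coverage and was kept in the pool. In the basal-like comparison, run on 2651 genes, 99.9% of genes changed 1.5-fold and 100% of those changed 2-fold were recovered, and intervals held the true ratio for 94.6% and 95.2% of them. In the secretory-lineage comparison, run on 2360 genes, the shares recovered were 89.2% and 99.5%. Over the whole libraries, run on 2719 genes, both were 100%. Of 400 lists without effect, 28, 24 and 17 in these comparisons lay outside the central range, and 20 of 20 lists raised 1.5-fold were called higher in each. A simulated background of 30% was estimated as 31.2% and 29.9% in the basal-like classes of the 8-week and pregnant libraries. The simulated classes made none of the marker genes themselves, so this does not test whether the real classes lack them. Thinning gave cycling shares of 13.3% at full depth and 13.0% with each UMI kept at a probability of 0.5, against 53.4% and 27.1% without thinning.

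Alternatives fixed in advance were all called barcodes; at least 1000 genes and under 5% mitochondrial UMIs; doublets kept; resolutions 0.5 and 2.0; both libraries clustered together; milk and cell-cycle genes left out of clustering; totals without milk, mitochondrial and ribosomal genes; TMM scaling (edgeR 4.0.16); 5% and 10% background subtracted; list minimums of 1 and 50 CPM; a pseudocount of 1 CPM; means of per-cell CPM; thinned sums; and other cycling limits. Added after seeing the data were a common UMI floor of 3039, the raw barcodes with at least 1000 UMIs, and the estimated background subtracted. A hormone-sensing comparison was planned but not made, since a class needed 30 cells in each library and the pregnant library held 0.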

Results

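Single-cell RNA profiles were made from reporter-marked mouse mammary cells in 2 libraries, 1 from 8-week-old mice and 1 from mice at pregnancy day 14.5. The series sets the marked cells at 8 weeks beside their descendants at a stage when the milk-producing lobules form. The 8-week library held 2604 called barcodes with 18920710 UMIs in all and a median of 5516 per barcode (range 3039 to 57408). The pregnant library held 8095 called barcodes with 56816954 UMIs and a median of 5823 (range 500 to 78480). After filtering, 2580 cells (median 5529 UMIs) and 6694 cells (median 6724.5 UMIs) remained; 15 and 1335 barcodes failed the filters, of which 862 pregnant barcodes had under 500 genes. There were no replicate libraries, so every difference is between these 2 libraries and no spread between animals could be measured.

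Nfatc1, the calcium-regulated transcription factor whose promoter drove the marking Cre, was lower in the pregnant library. Its summed level over all kept cells was 25.4 CPM (475 counts, interval 23.2 to 27.8) at 8 weeks and 9.11 CPM (495 counts, 8.33 to 9.95) in pregnancy, a ratio of 0.359 (0.316 to 0.408). The basal-like class held 57 and 306 counts (18.9 to 32.4 CPM and 6.83 to 8.58 CPM, ratio 0.307), and the vascular-like class, whose makeup differed between the libraries, 28.1 and 14.1 CPM (24.5 to 32.0 and 9.90 to 19.4). Intervals overlapped in the fibroblast-like class (30.1 CPM, 22.5 to 39.5, and 22.1 CPM, 18.6 to 26.1) and in the immune-like class, which was at 21.1 CPM and, on 4 counts, 33.4 CPM. Background RNA was expected to give 10.4 and 1.73 CPM of the basal-like levels. Subtracting it left a basal-like ratio of 0.325. Nfatc1 (ENSMUSG00000033016) lies on chromosome 18 at 80606205 to 80713071 on the minus strand of GRCm38. The secretory-lineage level was 19.6 CPM (17 counts) against 1.34 CPM (7 counts), and the 8-week hormone-sensing level was 9.53 CPM (6.33 to 13.8), an interval that held the level expected from background alone. The interval of the pregnant secretory-lineage level (0.541 to 2.77 CPM) held its background level of 0.702 CPM too.

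Basal-like cells, the contractile outer layer of the mammary epithelium, were the largest named class of the pregnant library and a small part of the 8-week library. They made up 66.2% of pregnant cells (4432 of 6694, interval 65.1 to 67.3%) and 12.7% of 8-week cells (328 of 2580, 11.5 to 14.1%). Secretory-lineage luminal cells, the branch that forms milk-producing alveoli, made up 3.82% (256 cells, 3.38 to 4.31%) and 2.79% (72 cells, 2.19 to 3.50%), with overlapping intervals. Hormone-sensing luminal cells, which carry the prolactin and steroid receptors, made up 6.47% of 8-week cells (167 cells). In pregnancy 0 of 6694 cells were so named. This allows a share of up to 0.0448% with 3 cells as the limit, or 0.0551% by the exact interval. Fibroblast-like cells made up 20.3% of the pregnant and 11.2% of the 8-week library. Vascular-like cells made up 8.37% (333 in endothelial and 227 in pericyte clusters) and 44.4% (1079 and 66), and immune-like cells 0.508% and 7.64%. The 8-week vascular split is uncertain. Its endothelial clusters of 167 and 138 cells were led by genes such as Ccl11 and Rgs5 or H2-M9 and Ednrb. These genes also led a pericyte cluster of the pregnant library, while Pecam1 was at 450 and 746 CPM in the 8-week clusters. Schwann-like and muscle-like clusters held 0.822% and 1.82%.

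Among epithelial-like cells alone, 94.5% of 4688 pregnant cells and 57.8% of 567 8-week cells were basal-like, 5.46% and 12.7% secretory-lineage, and 0 and 29.5% hormone-sensing. Clusters that scored best for endothelial markers, some of them led by genes of a pericyte cluster, held 41.8% of 8-week cells although the sort excluded CD31. The lowest called 8-week barcode had 3039 UMIs against 500 in the pregnant library. The sort and the barcode calling can therefore both set these shares. The 8-week basal-like class was 1 cluster; the pregnant class was 8 clusters, of which 1 with 568 cells was led by interferon genes such as Ifit1 and 1 with 218 cells by mitotic genes such as Top2a, apart from haemoglobin from 1 cell. In the 8-week library 334 cells stayed unnamed, 236 of them in 1 cluster whose leading genes included the smooth-muscle genes Myh11 and Myl9. When both libraries were clustered together, 0 8-week cells were named basal-like; 1 joint cluster of 335 cells scored best for basal markers but stayed unnamed because another class led its top genes.

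**Figure D1:**
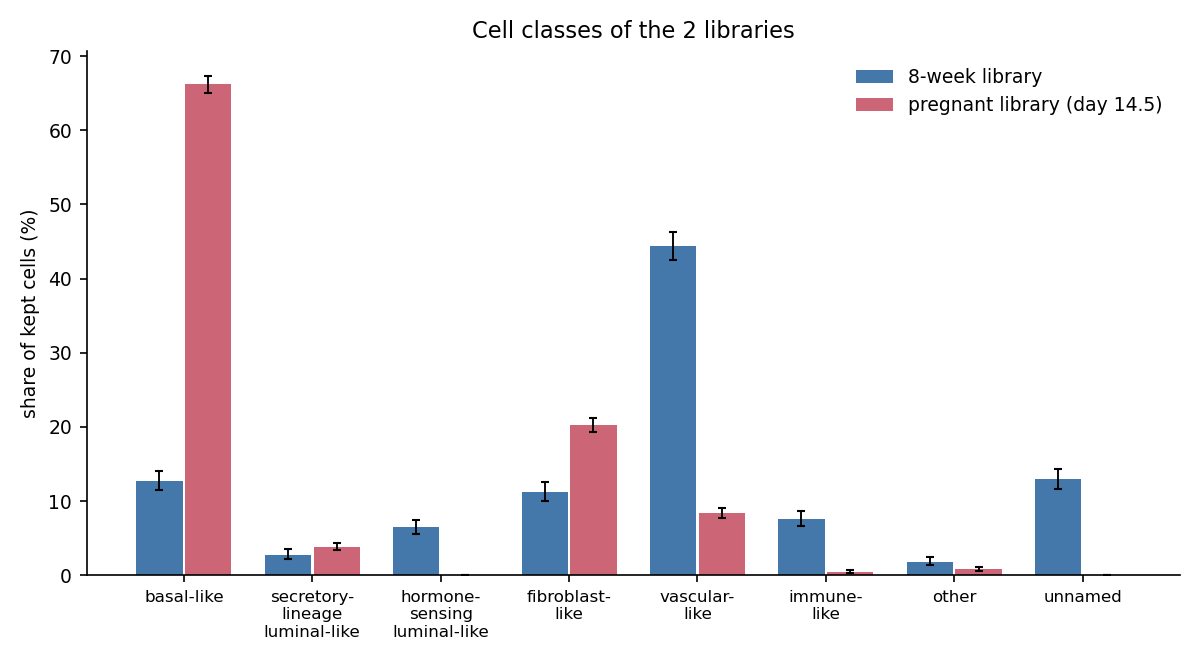
Share of kept cells (%, vertical axis) in each named class of the 8-week library (blue, 2580 cells) and the pregnant library (red, 6694 cells), with exact 95% intervals for counting error. The basal-like bar stands at 66.2% in the pregnant library against 12.7% at 8 weeks, and the vascular-like bar at 8.37% against 44.4%.

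In the basal-like class (2279831 counts at 8 weeks, 39896255 in pregnancy), Psat1, Psph, Mthfd2 and basement membrane genes were higher in the pregnant library, and 11 of the 12 lowest genes were also at a ratio of 0.5 or less in other classes. Psat1, an enzyme of serine synthesis, was 10.7-fold higher (7.23 to 16.5), Psph, the last enzyme of that pathway, was at 114 CPM against 17.5 CPM (ratio 4.77 to 9.11), and Mthfd2, a mitochondrial folate enzyme, was 6.17-fold higher (5.21 to 7.37). Eif4ebp1, a repressor of cap-dependent translation, was 6.44-fold higher (5.62 to 7.41). Mia, a small secreted protein known from melanoma and cartilage, stood at 483 CPM against 62.7 CPM, a ratio of 7.70 (6.53 to 9.14).

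Among the other genes ranked highest, Col7a1, the collagen of anchoring fibrils, was 4.76-fold higher (3.67 to 6.29). Col9a1, a cartilage collagen chain, was 33.3-fold higher on 4 8-week counts (13.0 to 122). Il17b, a cytokine, was 4.39-fold higher, Wif1, a secreted Wnt inhibitor, 5.30-fold, Reln, a secreted matrix glycoprotein, 4.98-fold, and Gpx2, a glutathione peroxidase, was at 134 CPM against 20.6 CPM. Gbp2b, an interferon-induced GTPase, had 0 counts at 8 weeks and 53.8 CPM in pregnancy. It was at least 40.9-fold higher by the rule of 3 counts and 33.2-fold by the exact interval. Gbp2b also had 0 counts over all kept 8-week cells and was at 0 CPM in the 8-week empty droplets. Of these 12, 9 were at least 2-fold higher as counted in the secretory-lineage, fibroblast-like and vascular-like classes and in the empty droplets. The exceptions were Mia, Psph and Col7a1. The pregnant empty droplets held 218 CPM of Il17b against 5.20 CPM at 8 weeks. Background can therefore raise such genes in other classes, and the ratios were not corrected for it. Background alone cannot account for all: pregnant fibroblast-like Gbp2b stood at 60.8 CPM, above the 48.5 CPM of the empty droplets. A difference between the libraries that acts on every cell type, such as the counting reference or software, is another candidate for the 9 genes. A change in every tissue would give the same. Mia (ENSMUSG00000089661) lies on chromosome 7 at 27179742 to 27181157, and Psat1 (ENSMUSG00000024640) on chromosome 19 at 15904678 to 15947337.

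The 12 lowest were led by AY036118, a long noncoding RNA on chromosome 17, at 975 CPM against 22.7 CPM (ratio 0.0233). Srp54b, a signal recognition particle gene with close copies whose ID the pregnant gene table names Srp54c, was at a ratio of 0.00503, Tonsl, a replication repair gene, at 0.00348, Ptprb, a receptor phosphatase of endothelium, at 0.00293, and Eno1b, a copy of enolase 1, at 0.00959. Fdx1l, a mitochondrial ferredoxin, had 1 pregnant count (0.000371, 9.33e-06 to 0.00210). Fam177a was at 0.0234, the septin Sept2 at 0.0273, the growth factor Tgfb1 at 0.0354, the synuclein Sncg at 0.0857 and the ubiquitin ligase Mid1 at 0.108. Of the 12 lowest, 11 were at a ratio of 0.5 or less in the 3 other classes and in the empty droplets too, with Sncg at 2.18 in the vascular-like class. The 2 libraries were counted on different gene tables, and reads of copies such as Srp54b and Eno1b can be split between genes. Tonsl (ENSMUSG00000059323) lies on chromosome 15 at 76626002 to 76639958.

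**Figure D2:**
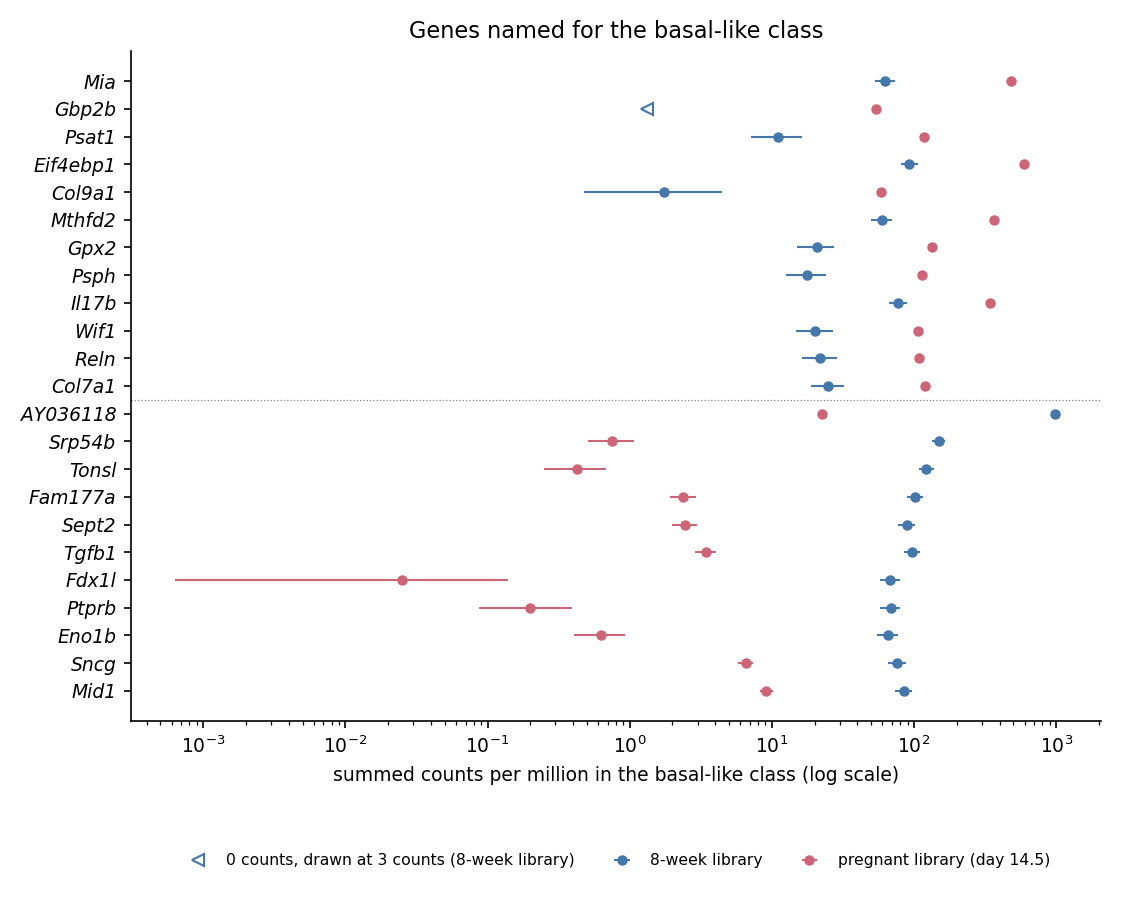
Summed CPM in the basal-like class (log scale, horizontal axis) of the 12 highest and 11 of the lowest ranked genes, in the 8-week library (blue) and the pregnant library (red), with exact Poisson 95% intervals; the open triangle marks 0 counts, drawn at 3 counts. Mia stands at 62.7 and 483 CPM, AY036118 at 975 and 22.7 CPM.

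Of the gene lists, 3 stood higher in the pregnant basal-like class than the central 95% of matched random lists. G2/M genes had a median log2 ratio of 1.20 (interval 0.88 to 1.29), with 8 of 9 measured members higher and 0 lower; the ubiquitin-conjugating enzyme Ube2c was 16.4-fold higher, on 4 8-week counts, and topoisomerase Top2a 9.58-fold (4.09 to 29.6). Basement membrane genes had a median of 0.61, with 5 of 15 higher and 0 lower, among them the type IV collagens Col4a1 (3.63-fold), Col4a2 (3.41-fold) and Col4a5 (3.47-fold) and the heparan sulphate proteoglycan Agrn (2.17-fold). Milk protein genes had a median of 1.18, with 5 of 9 higher and 4 lower: the caseins Csn2 and Csn1s2a were at 54.6 and 52.6 CPM from 0 counts, at least 41.5-fold and 40.0-fold higher, and both at 0 CPM once background was subtracted, while Glycam1 (0.0190) and lactoferrin Ltf (0.0202) were lower. With the estimated background subtracted, the milk median turned to -1.94, whereas the G2/M and basement membrane medians were 1.39 and 0.56. These medians were not over the same members, since the 10 CPM minimum was applied again. Csn2 and Csn1s2a, at 0 CPM, left the milk list, and 10 G2/M genes then counted as higher.

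Background RNA was estimated at 28.2% of the 8-week and 9.58% of the pregnant basal-like counts, and several lists moved with it. The pregnant estimate may be too high. Col1a1 was at 8.42 CPM in that class against 730 CPM in the empty droplets, and Cldn5 at 1.15 against 40.0 CPM, both a smaller share than 9.58%. Pecam1 went the other way, at 1.73 against 15.2 CPM. Subtracted pregnant levels, such as those of the caseins, may then be too low. The 7 lists below the central range were immediate early and dissociation genes (-0.97, 10 of 18 lower and 1 higher), antimicrobial genes (-0.99, 9 of 14 lower, 3 higher), interstitial matrix (-0.44, 8 of 18 lower), nutrient transport (-0.53, 4 of 12 lower), Notch (-0.50, 3 of 10 lower, 1 higher), prolactin signalling (-0.41, 4 of 12 lower, 1 higher) and fatty acid synthesis (-0.33, 3 of 14 lower, 1 higher). After subtraction the antimicrobial, interstitial and transport medians were -1.32, -0.37 and -0.37, and those of immediate early, Notch, prolactin and fatty acid genes were -0.06, -0.14, -0.21 and -0.04, inside the range. Among the immediate early genes the heat-shock gene Hspa1a was at 0.106 and the AP-1 gene Jund at 0.221, while Ctgf, a matrix-signalling protein, was 3.95-fold higher. Among antimicrobial genes the endotoxin receptor Cd14 was at 0.0369 and the neutrophil chemokine Cxcl2 at 0.176. The glucose transporter Slc2a1 was at 0.416, the signalling factor Stat5a at 0.450, the Notch ligand Jag2 4.59-fold higher and the desaturase Scd1 at 0.326. Other low ratios did not hold: the fibroblast collagens Col1a1 (0.104) and Col1a2 (0.105) were at 0 CPM in both libraries after subtraction, the prolactin receptor Prlr (0.0408) and Notch3 (0.0552) were under 1 CPM in both, and the kinase Jak2 (0.365) was at 0.910. Hspa1a stood at 0.495 after subtraction.

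The remaining basal-like lists lay inside the central range. Interferon genes had a median of 0.14, with 5 of 13 higher, such as Usp18 (4.27-fold) and Oasl2 (3.76-fold), and 2 lower; after subtraction the median was 1.38, above the range. Myoepithelial contraction genes had -0.05 with 2 of 15 higher (Cnn2 2.94-fold, Cald1 2.15-fold), turning to -0.36, below the range, after subtraction. Basal keratins and adhesion had 0.28, with the cadherin Cdh3 2.10-fold higher and Krt17 at 0.597; some of these genes named the class. Cell cycle inhibitors had -0.14, with Cdkn1a at 0.283 (0.446 after subtraction) and Cdkn1c 3.59-fold higher, and 0.26, above the range, after subtraction. Reported stem cell genes had -0.24, with the receptor Procr at 0.0655 and the cadherin Cdh5 at 0.00605. Both are also endothelial genes, and both were at 0 CPM in both libraries after subtraction. NFAT and calcineurin genes had -0.22, with the calcineurin inhibitors Rcan2 at 0.00301 and Rcan1 at 0.237 (0.458 after subtraction). Medians were -0.13 for Wnt genes (Wnt11 at 0.265), 0.02 for S phase (Mcm4 at 0.435), -0.09 for cholesterol synthesis (Msmo1 2.75-fold higher), -0.01 for ER folding (Pdia3 at 0.483), -0.15 for milk fat secretion (Cd36 at 0.0552, but 0 and 2.21 CPM after subtraction), 0.07 for mitochondrial transcripts and 0.07 for antigen presentation (H2-Aa at 0.0167, and 0.0696 after subtraction). The antigen presentation median was 0.32 after subtraction, at percentile 97.6 and so just above the range. The oestrogen and progesterone list had 4 measured members and no median.

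**Figure D3:**
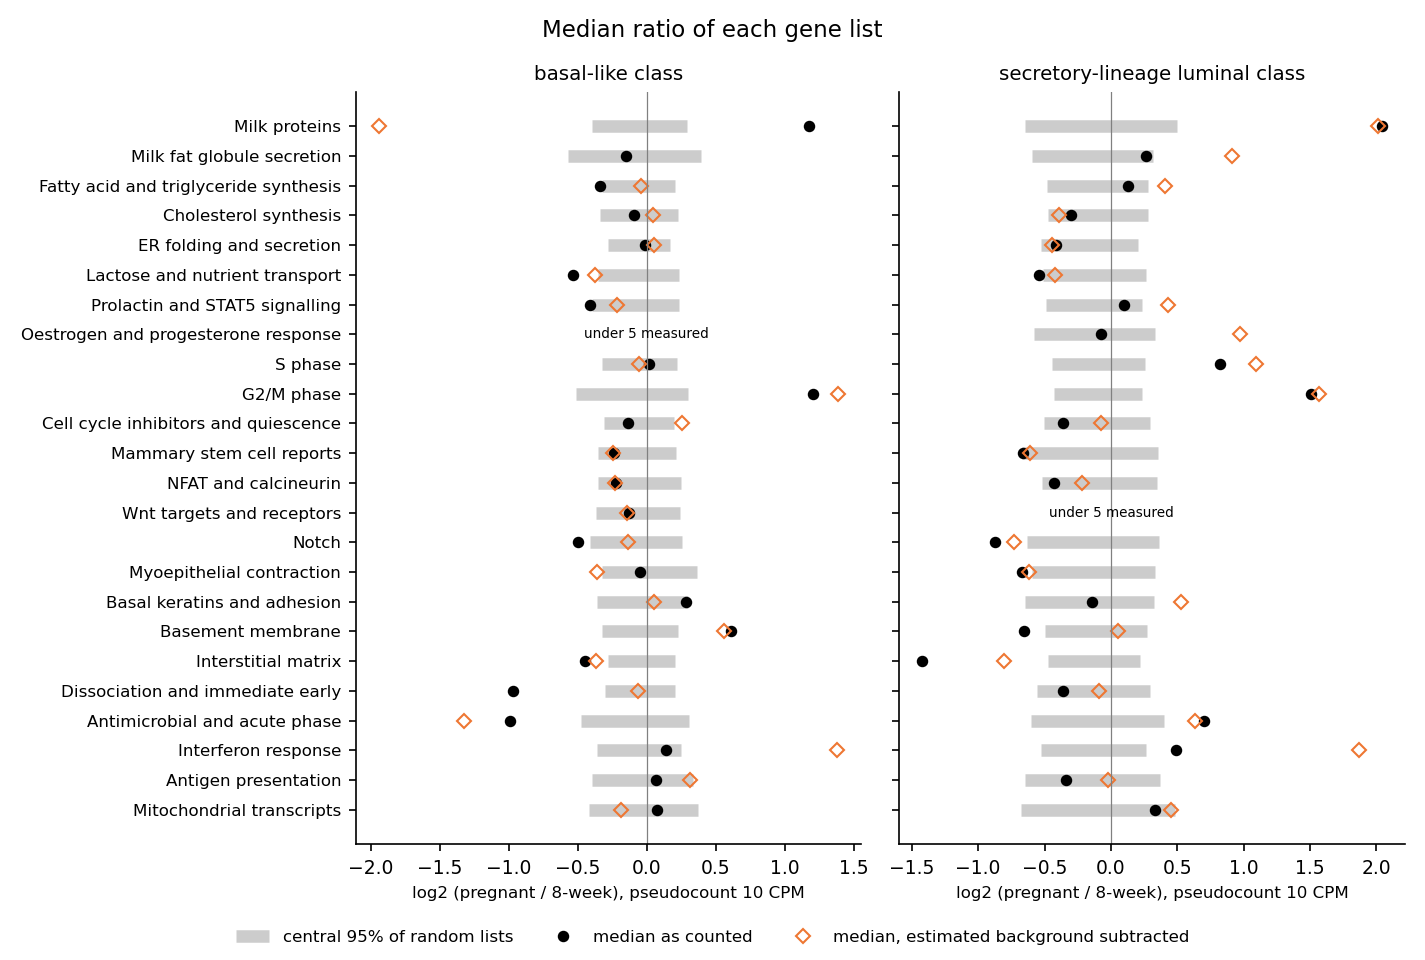
Median log2 ratio (pregnant over 8-week, horizontal axis) of each gene list in the basal-like and secretory-lineage classes, as counted (black dots) and with estimated background subtracted (orange diamonds), over the central 95% of matched random lists (grey bars). The basal-like milk protein median moves from 1.18 to -1.94 and the interferon median from 0.14 to 1.38. Measured members can differ between dots and diamonds.

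In the secretory-lineage class (865801 counts at 8 weeks from 72 cells, 5205462 in pregnancy from 256), casein and proliferation genes were higher in the pregnant library. Csn2, beta-casein, had 0 counts at 8 weeks and 17180.4 CPM in pregnancy, at least 4958-fold higher by the rule of 3 counts and 4032-fold by the exact interval. Csn1s2a stood at 2.31 CPM (2 counts) and 17534 CPM, and Csn1s1 at 1.16 CPM (1 count) and 6171 CPM, with ratios of 7591 (2101 to 62680) and 5343 (959 to 211026). Whey acidic protein Wap and the fatty acid carrier Fabp3 had 0 counts at 8 weeks and 152 and 811 CPM in pregnancy, at least 44.0-fold and 234-fold higher. The caseins were also among the markers that named this class, and the classes were led by Aldh1a3 and Csn3 at 8 weeks and by caseins in pregnancy; the median of the milk list was 2.04 as counted, with 8 of 13 members higher and 2 lower, and 1.95 with genes at 0 counts set to their bound.

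The other genes ranked highest included innate defence genes: the acute-phase proteins Saa1 (38.3-fold, 14.9 to 141) and Saa2 (27.0-fold, 12.4 to 73.8), which are close copies, S100a8 (10.8-fold), the chemokine Ccl20 (43.5-fold, 18.6 to 134) and the protease inhibitor Wfdc12 (0 counts to 165 CPM, at least 47.7-fold). Cited4, a transcriptional co-activator, was 12.2-fold higher (7.13 to 23.1) and Ube2c 22.8-fold (10.4 to 62.2). The lowest included the protease inhibitor Cst3 (0.0482), tissue factor F3 (0.0757), the prostaglandin synthase Ptgs2 (0.0471) and the peptide hormone Cck (0.0838). Also lowest were genes low in the basal-like class: AY036118 (0.0176), Fam177a (0.0161), Srp54b (0.00792), Tonsl (0.0198) and Sept2 (0.0143), and Fdx1l and Ptprb, which had 0 pregnant counts and were at least 152-fold and 134-fold lower. Pnp ranked among them only because the pregnant gene table gave that symbol another ID, absent at 8 weeks; with the counts of both IDs its ratio was 0.830. Csn2 (ENSMUSG00000063157) lies on chromosome 5 at 87692624 to 87699630 and Csn1s2a (ENSMUSG00000061937) at 87774567 to 87788797.

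All 25 measured G2/M genes were higher in the pregnant secretory-lineage class, with a median log2 ratio of 1.51 (1.49 with genes at 0 counts set to their bound); Birc5, a mitotic survival gene, was 26.5-fold higher (9.01 to 129) and the kinase Cdk1 33.3-fold (9.17 to 276). S phase genes had a median of 0.82 with 12 of 16 higher and 0 lower, such as the helicase subunit Mcm6 (4.66-fold). Antimicrobial genes had 0.70, with 6 of 15 higher and 4 lower (Ltf 0.183), and interferon genes 0.49, with 4 of 13 higher (Oasl2 3.91-fold) and 2 lower (Ifitm3 0.316, and 0.732 after subtraction). After subtraction of background, 25.2% at 8 weeks and 3.88% in pregnancy, these medians were 1.56, 1.10, 0.64 and 1.87. With a list minimum of 50 CPM the antimicrobial and interferon medians were -0.07 and -0.11.

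Lists below the range in this class were interstitial matrix (-1.42, 13 of 18 lower; Igfbp5 0.115, Dcn 0.154), Notch (-0.87, 5 of 9 lower and 1 higher; Nrarp 0.184, Hes1 2.35-fold higher), myoepithelial contraction (-0.67, 6 of 13 lower, 1 higher; Myl9 0.253), basement membrane (-0.65, 6 of 13 lower; Sparc 0.377) and nutrient transport (-0.54, 5 of 13 lower; Slc2a1 0.228). After subtraction they were -0.80, -0.73, -0.62, 0.05 and -0.42, the last 2 inside the range, and Dcn and Sparc were at 0 CPM at 8 weeks and 7.99 and 56.3 CPM in pregnancy. Lists inside the range as counted were milk fat secretion (0.26, 0.91 after subtraction; Plin2, the lipid droplet coat, 2.73-fold higher), fatty acid synthesis (0.13; Thrsp 4.63-fold higher), cholesterol synthesis (-0.30; Fdft1 4.96-fold higher), ER folding (-0.42; Hspa5 0.320), prolactin signalling (0.10, 0.43 after subtraction; Elf5 1.84-fold), oestrogen and progesterone (-0.08, 0.97 after subtraction; Calca 63.9-fold on 1 8-week count, 11.4 to 2529; Areg 0.184, and 0.313 after subtraction), cell cycle inhibitors (-0.36; Cdkn1a 0.136), stem cell genes (-0.66; Procr 0.0326, at 0 CPM in both libraries after subtraction), NFAT genes (-0.43; Rcan1 0.232, and 0.429 after subtraction), basal keratins (-0.14, 0.53 after subtraction; Krt5 2.61-fold higher, at 0 CPM at 8 weeks after subtraction), immediate early genes (-0.36; Nr4a1 0.270), antigen presentation (-0.34; Cd74 0.0353, and 0.307 after subtraction) and mitochondrial transcripts (0.33). After subtraction the milk fat, prolactin and oestrogen and progesterone medians lay above the range. As counted, 1 of 14 fatty acid genes was higher and 3 were lower. Of 15 prolactin genes 1 was higher and 4 were lower, and Elf5 did not reach the 2-fold limit. Wnt genes had 3 measured members.

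Summed over all kept cells, a measure that needs no class names but mixes cell makeup with change inside classes, caseins and basal-cell genes were higher in the pregnant library. Csn2 had 0 counts at 8 weeks and 1700 CPM in pregnancy, at least 10595-fold higher, Csn1s2a was at 0.160 CPM (3 counts) and 1733 CPM, and Csn1s1 was 310-fold higher (225 to 441). The others ranked highest were Mia (22.6-fold), Il17b (19.8-fold), Ctgf (15.4-fold), the apolipoprotein Apoc1 (11.1-fold), Gpx2 (21.4-fold), Wif1 (31.1-fold), Col9a2 (12.8-fold), Col7a1 (14.3-fold) and Fabp3 (18.2-fold). The lowest were the hormone-sensing cell genes Pcp4 (0.00741) and Gpx3 (0.0369), the antigen-presenting genes H2-Aa (0.0114), H2-Ab1 (0.0196), H2-Eb1 (0.0131) and Cd74 (0.0506), the cytokine Il1b (0.0154), the endothelial junction gene Cldn5 (0.0460), and AW112010 (0.0429), Lrg1 (0.0448) and AY036118 (0.0226). Pnp ranked with them through the same difference of IDs, and with both IDs its ratio was 0.455.

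By list, the whole-library medians were above the range for basal keratins (1.47, 9 of 12 higher; Krt5 6.31-fold), contraction (1.41, 10 of 15 higher; Actg2 4.91-fold), basement membrane (1.02, 9 of 16 higher, 1 lower; Lama3 6.16-fold), Wnt genes (1.0, 6 of 8 higher; the receptors Fzd1 and Fzd7 3.96-fold and 3.99-fold), milk proteins (0.86, 7 of 12 higher, 2 lower) and G2/M (0.54, 4 of 11 higher). Below it were oestrogen and progesterone genes (-1.30, 7 of 8 lower; the growth factor Areg 0.0577), immediate early genes (-1.18, 11 of 18 lower, 1 higher; Hspa1a 0.0781), nutrient transport (-0.51, 5 of 12 lower), cell cycle inhibitors (-0.50, 6 of 17 lower, 2 higher) and fatty acid synthesis (-0.47, 7 of 15 lower), which was inside the range at -0.28 after subtraction. The other medians were 0.07 for milk fat secretion, -0.09 for cholesterol synthesis, 0.01 for ER folding, -0.27 for prolactin signalling, 0.15 for S phase, 0.28 for stem cell genes, -0.34 for NFAT genes, -0.32 for Notch, 0.20 for interstitial matrix, -0.28 for antimicrobial genes (0.03 after subtraction), -0.24 for interferon genes (0.08), -0.39 for antigen presentation and 0.12 for mitochondrial transcripts. TMM scaling would raise every log2 ratio by 0.17 in the basal-like class, 0.23 in the secretory-lineage class and 0.12 over the whole libraries.

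A larger share of pregnant than of 8-week basal-like cells carried 3 or more G2/M UMIs: 10.2% (418 of 4117, interval 9.25 to 11.1%) against 1.55% (5 of 322, 0.506 to 3.59%), with all cells thinned to 3300 UMIs and 315 and 6 shallower cells left out. Secretory-lineage shares were 33.6% (78 of 232, 27.6 to 40.1%) and 11.4% (8 of 70, 5.07 to 21.3%). Vascular-like shares, over cells of different makeup, were 17.3% and 3.60%, and fibroblast-like shares 2.41% and 1.17%, whose intervals overlapped. The 8-week hormone-sensing share was 16.9%, and over all kept cells the shares were 10.5% and 6.31%. Background RNA was expected to give 0.168 G2/M UMIs per thinned pregnant basal-like cell and 0.281 per 8-week cell. The summed G2/M level of the basal-like class was 546 CPM and 182 CPM. Without thinning the basal-like shares were 35.2% and 15.9%.

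**Figure D4:**
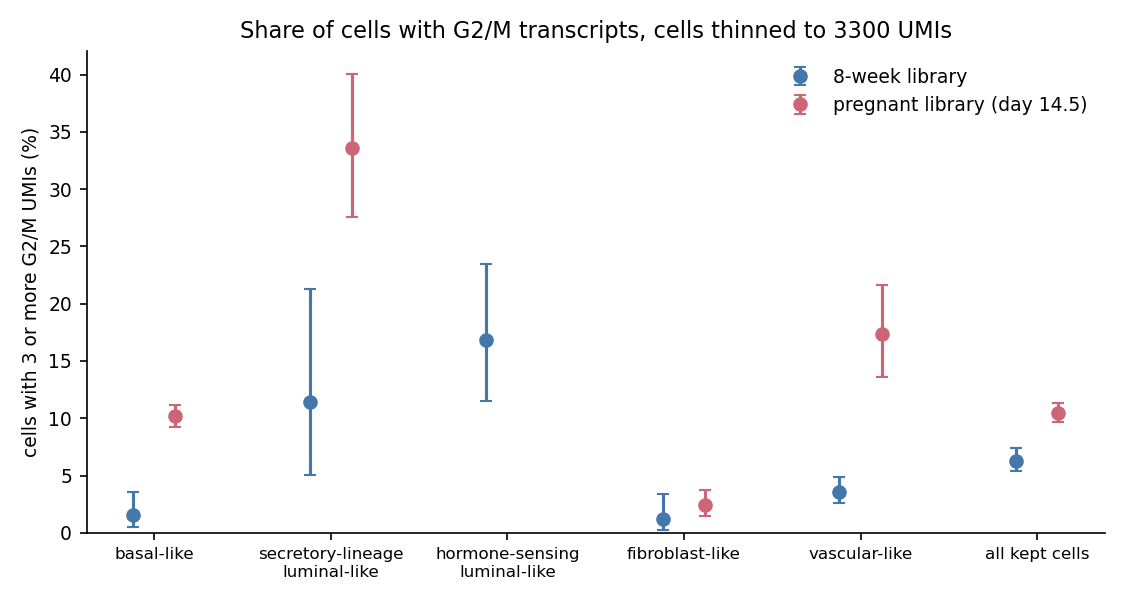
Share of cells with 3 or more G2/M UMIs (%, vertical axis) by class after thinning to 3300 UMIs per cell, in the 8-week (blue) and pregnant (red) libraries, with exact 95% intervals. Basal-like cells stand at 1.55% and 10.2%, and secretory-lineage cells at 11.4% and 33.6%.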

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

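The tests of the epithelial-like share were chosen only after the result was seen. In the 8-week library 1822 barcodes outside the called list held 1000 or more UMIs, up to 3035, where the pregnant library had 71; these barcodes were used only in the alternative with raw barcodes, not in the main comparisons.

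Epithelial-like cells were 22.0% of the 8-week and 70.0% of the pregnant library, and basal-like cells 12.7% and 66.2%. The tables argue against the different UMI floors as the whole cause, since with the 8-week floor applied to both libraries the pregnant basal-like share was 63.0%. They also argue against background RNA giving epithelial cells a vascular name, since Epcam, which stood above the empty droplets in every 8-week epithelial-like class, was in the vascular-like class at 0.276 times its CPM in them. A difference in the sort, in tissue digestion or in the number of marked epithelial cells between 8 weeks and pregnancy stays open, and no value here separates them.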

How the results depend on the processing

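The common UMI floor, the raw barcodes and the estimated background were tests chosen only after the results were seen. Of the values of class shares, cycling, Nfatc1 and numbers of lists under the alternatives, 181 stayed within the main interval or 1.5 times the main number and 44 moved; values of named genes and list members kept the sign of the main value in 4644 cases of a main log2 of 1 or more either way and in 1511 of a smaller one, and took the other sign or 0 in 25 and 13. The whole-library Nfatc1 log2 ratio of -0.89 lay between -1.38 and -0.74 in 19 alternatives. List medians took the other sign in 4 cases and kept it in 182 where the main log2 was 1 or more either way, and in 70 against 1027 where it was smaller. The pregnant basal-like share was 57.6% with all called barcodes, 71.2% with 1000 genes and 5% mitochondrial UMIs, 50.4% with doublets kept, 52.7% at resolution 2.0, 63.0% with the same UMI floor and 55.3% with raw barcodes of 1000 UMIs; clusters with best basal markers but left unnamed held 823, 1024, 904, 565 and 760 pregnant cells with all barcodes, doublets kept, resolution 2.0, the same floor and raw barcodes. With the libraries clustered together the 8-week basal-like share was 0 and 1 cluster of 335 cells with best basal markers stayed unnamed, so no basal-like comparison was possible there, and the pregnant hormone-sensing share was 0.0598%. With raw barcodes the 8-week basal-like and hormone-sensing shares were 8.25% and 2.88%. Basal-like cycling in pregnancy was 12.04% with doublets kept, 11.98% at resolution 2.0, 11.7% with the same floor, and 3.72% and 11.8% at 8 weeks and in pregnancy with raw barcodes; the cause was not tested. It was 10.6% and 22.5% at 2 or more G2/M UMIs, 0 and 5.42% at 5 or more, and 15.9% and 35.2% unthinned. Basal-like lists higher were 5 with doublets kept, and whole-library lists lower were 8 with cells thinned; the cause was not tested. With estimated background subtracted, 5 basal-like and 8 secretory-lineage lists were higher and 3 secretory-lineage lists lower; the basal-like milk median was -1.94, as it was -2.80 and -3.28 with 5% and 10% subtracted, and the secretory-lineage basement membrane median was 0.051. With 5%, 10% and the estimated background subtracted, Csn2 and Csn1s2a in the basal-like class were at a log2 ratio of 0. With the estimated background subtracted, basal-like Cdh5, Col1a1, Col1a2, Lum and Procr and secretory-lineage Procr were also at 0. Basal-like genes with a main log2 of 1 or more either way that turned were Nrarp (0.0033), Pmvk (0.021), Prlr (0.069), Cd36 (0.29), Notch1 (0.68) and Hspa1b (0.93). Genes with a smaller main log2 that turned included Insig1 (0.15) and Plin2 (0.46). Secretory-lineage genes with a main log2 of 1 or more either way that turned were H2-Eb1 (0.16), Elovl5 (0.47), Hspa1a (0.48), Ifi27l2a (0.75), Dcn (0.85), Hspa1b (1.32) and Sparc (2.73). With a minimum of 50 CPM, which leaves fewer members, 1 basal-like list was higher and 2 lower, 3 secretory-lineage lists were higher and 1 lower, the basal-like milk median was -0.048, and the secretory-lineage antimicrobial and interferon medians were -0.066 and -0.11. Scrublet marked 2 pregnant cells with 1000 genes and 5% mitochondrial UMIs, and 2 pregnant cells with the same floor, and was taken not to have worked there. It marked 2 8-week cells with raw barcodes, so few doublets were removed there. No paired analysis was possible because each group had 1 library. The 72 8-week secretory-lineage cells limit the depth of that comparison.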

Other observations

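The comparison of fibroblast-like cells, the tests of shared low genes, of their background and of the number without an overlapping gene, and the depth and background tests of cycling were chosen only after the results were seen; the tests of sums with overlapping genes, doublets and ATF4 targets were set before theirs. Fibroblast-like cells (290 at 8 weeks, 1357 in pregnancy) had higher levels of interferon and basement membrane genes in the pregnant library. Cxcl10, an interferon-induced chemokine, was 12.7-fold higher (11.2 to 14.4), Cmpk2, an interferon-induced nucleotide kinase, 11.9-fold, and Gbp2b at least 35.0-fold. Gbp2b had 0 counts over all kept 8-week cells. For that gene a difference between the libraries such as the counting reference cannot be told apart from a change in expression. The interferon list had a median log2 ratio of 0.67 with 6 of 13 members higher and 0 lower. The basement membrane list had 0.60 with 5 of 13 higher and 1 lower, including Col4a1 at 5.38-fold (4.88 to 5.95). With background subtracted these medians were 0.92 and 0.74. The acute-phase gene Saa3 and the anchoring collagen Col7a1 were each 9.33-fold higher, the growth factor ligand Ereg 13.5-fold, and the hormone Fgf21 39.8-fold on 5 8-week counts (17.0 to 123). Of these, Cxcl10, Gbp2b, Col7a1 and Fgf21 were at least 2-fold higher in the basal-like and vascular-like classes and in the empty droplets too. Those ratios were as counted, and background can carry genes of 1 class into others. A difference between the libraries that acts on every cell type is a candidate for these genes too.

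Lower in pregnant fibroblast-like cells were the matrix genes Thbs4 (736 CPM against 35.7 CPM, ratio 0.0485), Col8a1 (0.0163) and Aspn (0.111), the growth factor Ptn (0.0955), and C1qtnf3 (0.0714), Angptl1 (0.0426) and the chemokine Ccl5 (0.0614). Of these, Thbs4, C1qtnf3, Angptl1 and Ccl5 were also at a ratio of 0.5 or less in the basal-like and vascular-like classes and in the empty droplets. Those ratios too were not corrected for background. Cholesterol synthesis genes had a median of -0.52 with 6 of 15 lower and 0 higher, and S phase genes -0.54 with 3 of 8 lower; both stayed below 0 with background subtracted, at -0.56 and -0.40. The interstitial matrix median of 0.48 was 0.14 with background subtracted. The makeup of the fibroblast-like class may differ between the libraries. An 8-week cluster of 112 cells was led by Thbs4, and C1qtnf3 was among the leading genes of another with 108 cells. Neither gene was among the 10 leading genes of a pregnant fibroblast-like cluster. Changes inside fibroblast-like cells, up or down, cannot be told apart from a different mix of them.

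Of the 12 genes lowest in the pregnant basal-like class, 11 were at a ratio of 0.5 or less in the secretory-lineage, fibroblast-like and vascular-like classes and in empty droplets. A difference that acts on every cell type, such as the counting reference or software, is a candidate explanation; a change in every tissue would give the same. With background RNA subtracted the median ratio of the 12 was 0.0201, but this cannot decide whether background of the 8-week library played a part. The naming rule had kept only genes at 0.5 or more of the 8-week empty-droplet CPM, above the 28.2% background share. A low ratio was thus fixed in advance. Reads given to an overlapping gene on the same strand were examined with the vM21 annotation, in which 9 of the 12 had no such partner. This argues against overlap for most only so far as vM21 holds the genes of both counting tables. The pregnant table alone held a second ID for the symbols Sept2 and Srp54b, both with 0 pregnant counts. For the other 3 genes overlap cannot be told apart from other causes, since a read that matches 2 genes can also be dropped. The sum with Vps28 was at a ratio of 0.559 for Tonsl, and the sums for Sept2 and Fdx1l were at 0.0274 and 0.0119.

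More pregnant than 8-week basal-like cells had 3 or more G2/M UMIs. Depth is argued against, since the pregnant share after thinning was 10.2% and the upper bound at 8 weeks 3.59%, and background RNA, since it would give 0.168 G2/M UMIs per pregnant cell and 0.281 per 8-week cell. Doublets with secretory-lineage cells are argued against, since the caseins in these cells were 0.314% of the secretory-lineage level (129 against 40885.5 CPM). Against more division of basal-like cells in pregnancy, the S phase median was 0.02 with 0 of 14 members higher and 2 lower. The larger share was not limited to basal-like cells (vascular-like 17.3% against 3.60%); more division may remain as a hypothesis, and a difference between animals stays open.

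Psat1, Psph, Mthfd2 and Eif4ebp1, all higher in the pregnant basal-like class, are known targets of the stress-response factor ATF4, and a wider ATF4 programme may be higher as well. A list of 24 other ATF4 targets had a basal-like median of 1.08 at percentile 100 of matched random lists, with 15 of 22 measured members higher and 4 lower. Aldh18a1 was 7.95-fold higher and Asns 2.85-fold, while Ddit3 was at 0.428 and Nupr1 at 0.243. The medians were 0.59 in the secretory-lineage and 0.68 in the fibroblast-like class, so the pattern was not limited to basal-like cells, and an effect of tissue handling stays open.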
